A study of Mus musculus with 6 samples.

How the data were processed

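RNA from 6 mouse samples was measured by RNA sequencing: 2 of mouse embryonic fibroblasts (MEF), 2 of muscle, and 2 of cells made by direct reprogramming, called transdifferentiated cells here. The sample titles gave the group and the replicate number of every sample. Per the labels' protocols, total RNA was isolated with a Qiagen column kit, libraries were made with the Lexogen SENSE mRNA-seq kit V2, which selects polyadenylated RNA and keeps strand, and single-end reads of 75 bp were sequenced on a NextSeq 500. The factor used for conversion, the age or source of the muscle, the time after conversion and whether replicates came from separate cultures or animals are not given in the sources used here. The p-values therefore measure the spread between these samples, which may be technical.

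The authors deposited whole-number read counts per gene symbol for each library, with no normalization. The genome build mm10 and the tools Trim Galore 0.6.0, HISAT2 2.1.0, featureCounts 1.6.2 and DESeq2 1.26.0 are named in the submitters' processing notes, without roles or settings. The gene annotation and the strand setting of the counting are not given in the sources used here. Genes that overlap or lie antisense to another gene, and genes with near-identical copies such as the actins and the clustered myosin heavy chains on chromosome 11, are therefore uncertain where the counting could split or share their reads. Transcripts of an introduced factor with a mouse coding sequence would be counted with the endogenous gene.

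A deposited table of the authors' own comparison gives a log2 fold change with its standard error, a p-value and an adjusted p-value for 2806 genes, per the file headers. Its header names no contrast. In all of the 2645 listed genes tested here, the authors' sign was that of MEF over muscle, and the smallest log2 fold change in size was 2.00 and the largest adjusted p 0.0493. A further column with a mean over libraries could not be matched to libraries and was not used here.

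The count table held 55286 symbols, of which 24642 had 0 counts in every library. Total counts were 18997705 and 18978216 in MEF, 24584951 and 16952000 in muscle, and 16817033 and 21072555 in transdifferentiated cells. The 10 most abundant genes took between 9.07% and 11.1% of a library. A count of 0 allows an upper limit of 3 counts, between 0.128 and 0.183 CPM in a single library. For a group whose 2 libraries were both at 0, the bound used for "at least" folds is the mean of its 2 libraries' limits, 0.155 CPM for both MEF and muscle. Where a group held 1 to 3 counts in all, the ratio is given with its exact Poisson interval at 95 percent, which covers counting error only.

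Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr by group (17400) were scaled by TMM and fitted with all 6 libraries in a single quasi-likelihood model with group as its term (robust, legacy dispersion), which leaves 3 residual degrees of freedom. Each of the 3 comparisons was tested with the quasi-likelihood F test, Benjamini-Hochberg adjusted over the tested genes, and a gene was called at an adjusted p under 0.05. Values per group are CPM (counts relative to the library total, from the cpm function of edgeR) with TMM factors, as mean ± SD with n = 2, and log2 fold changes are given as value ± SE. The biological coefficient of variation was 27.3%. An exact permutation test of 2 against 2 libraries cannot give a two-sided p under 0.333, so single genes rest on the model. Coordinates are from GENCODE release M21 on the mm10 assembly, matched by symbol; 53289 symbols matched.

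There were 40 gene lists with 876 genes, of which 874 are in the count table, and 39 lists had at least 3 tested genes. Each list was tested in each comparison with camera from limma 3.58.1 at an inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated. With an estimated correlation 5 lists kept their call in transdifferentiated cells against MEF (the core, embryonic, fast and slow sarcomere lists and muscle energy metabolism), 10 in muscle against MEF and 1 (macrophage markers) in transdifferentiated cells against muscle, which was 0 with a GC offset as well. The lists, designs, tests and a rule for the genes named in the text were fixed before the data were examined. Under that rule the named genes are, for each comparison, the 8 with the largest fold change in each direction at 20 CPM or more with replicates that do not overlap, a fixed panel of 38 muscle, fibroblast, cell-cycle and DNA methylation genes, and the 3 members of each list with the smallest adjusted p plus 1 called against the list's majority. It further takes genes set apart across the comparisons: 6 higher in muscle than in both others, 6 shared by MEF and transdifferentiated cells, and 8 above and 8 below both others in transdifferentiated cells. Genes named outside the rule are marked where they appear.

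The distance covered is the log2 fold change of transdifferentiated cells over MEF divided by that of muscle over MEF, per gene called between muscle and MEF with a log2 fold change of at least 1. For a single transdifferentiated library it was computed from log2 CPM with a small offset against the means of MEF and muscle. Because both comparisons use the same 2 MEF libraries, an unchanged group was simulated against them 20 times.

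The steps were first tested on simulated counts with the real means and library sizes and a seeded set of changed genes. For transdifferentiated cells against MEF (15541 genes fitted), 5.88% of genes changed by 1 on the log2 scale were recovered, 69.7% of those changed by 2 and 95.5% of those changed by 4. For muscle against MEF (15473 genes) the shares were 2.94%, 83.3% and 95.5%, and for transdifferentiated cells against muscle (15863 genes) 10.3%, 78.8% and 92.3%. Wrong calls made up 5.04%, 9.09% and 3.25% of the calls. Of 40 random lists per comparison, 0, 1 and 0 had a camera p under 0.05, and a simulated distance of 50% came out at 49.8% for genes set higher and 49.6% for genes set lower (15372 genes). Every changed gene in that distance check had a log2 fold change of 4 in size. It therefore does not cover genes selected near the threshold of 1, which the reported shares include. In this simulation most changes near 1 on the log2 scale went uncalled. Only 65 to 68 genes of each fold size were changed there, far fewer than the 6198 called between muscle and MEF. The adjusted threshold was therefore stricter in the simulation, and its shares may understate what the data could recover. In the data 33 of 47 oxidative phosphorylation genes, with a median of 1.12, were called higher in muscle than in MEF. A gene that was not called is still not shown to be equal.

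Alternatives fixed before the data were examined were other scalings (RLE, upper quartile, library size), other count filters, DESeq2 1.42.0, limma-voom, other dispersion settings, fits of the 2 compared groups alone, the replicate number as a block, other thresholds and leaving out each library. An offset for the GC content of transcripts, known for 97.9% of tested genes, was added after replicates were seen to differ along GC content. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.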

Results

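Gene expression was compared between mouse embryonic fibroblasts, muscle and cells converted from fibroblasts to muscle by direct reprogramming, to ask how far conversion replaces the fibroblast expression state with that of muscle. Each group had 2 libraries, with 16817033 to 24584951 counted reads. Replicates were the most similar pairs, with Spearman correlations of log2 CPM of 0.976 in MEF, 0.984 in muscle and 0.972 in transdifferentiated cells. Transdifferentiated cells lay closer to muscle (0.922 to 0.938) than to MEF (0.834 to 0.860), and muscle and MEF lay farthest apart (0.801 to 0.821). Replicates differed by more than counting noise in every group, with chi-square per degree of freedom of 66.4, 37.1 and 61.6. The p-values measure the spread between these samples, which may be technical.

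Muscle and MEF, the reference cell types, differed across the contractile apparatus and its regulators. Myod1 (chromosome 7, 46376474 to 46379099), which starts the muscle programme, was at 0.983 ± 0.635 CPM in MEF and 673 ± 72.2 CPM in muscle (SD, n = 2), and Myog, needed for terminal differentiation, at 1.41 ± 0.271 and 1047 ± 77.9 CPM. Of 20 myogenic regulators 17 were higher in muscle over all genes tested and 17 adjusted over the list alone, 0 were lower and 3 were neither (camera adjusted p = 1.7e-19). The sarcomere genes rose together. Of 34 core sarcomere genes 33 were higher (33 adjusted over the list alone, median log2 fold change 9.50, camera adjusted p = 7.9e-80), and Tpm1 was the 1 that was not called, a name chosen after its values were seen. All 18 adult fast fibre genes and all 8 embryonic and neonatal sarcomere genes were higher (camera adjusted p = 1.9e-55 and 5.9e-37), as they were adjusted over the list alone. Titin (Ttn, chromosome 2, 76703980 to 76982547) rose by 10.41 ± 0.41 on the log2 scale (SE) and embryonic myosin Myh3 by 9.82 ± 0.49 (edgeR adjusted p = 9.6e-07 and 2.6e-06). The energy genes rose in 24 of 24 cases (camera adjusted p = 2.4e-38), among them the muscle creatine kinase Ckm, which went from 0.777 ± 0.06897 to 989 ± 71.8 CPM. Oxidative phosphorylation genes rose less, with 33 of 47 higher (36 adjusted over the list alone), 14 neither and a median of 1.12 (camera adjusted p = 7.6e-06). For that list the adjusted p = 0.227 with an estimated correlation.

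Most cell-cycle, fibroblast identity, interferon response and macrophage genes were lower in muscle than in MEF. Of 45 cell-cycle genes 42 were lower, over all genes and adjusted over the list alone, 1 was higher and 2 were neither (median -3.67, camera adjusted p = 2.5e-22). The call was lost with an adjusted p = 0.0767 with an estimated correlation. The proliferation marker Mki67 was at 76.4 ± 15.1 CPM in MEF and 1.81 ± 0.402 CPM in muscle, while Cdk2 was the 1 member above MEF in muscle (1.17 ± 0.25, edgeR adjusted p = 0.00672; adjusted p = 0.0679 without Muscle replicate 2). Fibroblast identity genes were lower in 22 of 34 cases (23 adjusted over the list alone) and higher in 4, with 8 neither (median -2.23, camera adjusted p = 4.5e-08). The surface markers Thy1 and Ly6a had log2 fold changes of -5.10 ± 0.40 and -5.60 ± 0.34 (SE; edgeR adjusted p = 2.4e-05 and 6.3e-06), and the 4 higher members were the transcription factors Tbx15, Tcf4, Zeb1 and Runx1, the last 3 named after their values were seen. Extracellular matrix genes were lower in 30 of 44 cases (33 adjusted over the list alone, 0 higher, 14 neither, camera adjusted p = 2.9e-08), with adjusted p = 0.315 with an estimated correlation. Hox genes, which record position along the body axis, were lower in 21 of 37 cases (23 adjusted over the list alone, 0 higher, 16 neither, camera adjusted p = 1.0e-08), with adjusted p = 0.227 with an estimated correlation. Interferon response genes fell in 21 of 27 cases (22 adjusted over the list alone, 6 neither, median -2.84, camera adjusted p = 4.6e-08). Macrophage and leukocyte markers, which stood at a median of 3.004 CPM in MEF and 0.1797 CPM in muscle, moved the same way, with 14 of 17 lower (14 adjusted over the list alone), 1 higher and 2 neither (median -4.54, camera adjusted p = 7.6e-08). Markers of other cell types were also lower. These were 8 of 11 endothelial, 7 of 8 tendon and cartilage and 4 of 6 adipocyte markers (camera adjusted p = 6.1e-04, 1.7e-04 and 0.00357). Adjusted over the list alone the counts were 8, 7 and 5. These list calls were lost with an estimated correlation (adjusted p = 0.0981, 0.203 and 0.126). In these lists 1 endothelial marker and 1 tendon and cartilage marker were higher.

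Over all 17400 tested genes 3009 were higher and 3189 lower in muscle than in MEF (edgeR, adjusted p under 0.05). Without Muscle replicate 1 the lower count was 2118, and without Muscle replicate 2 the counts were 1980 and 1778. Of the 2806 genes in the authors' deposited table, 1566 were higher in MEF and 1240 in muscle. All 2645 of them tested here moved in the direction of the authors' deposited table, and 2628 were called here. The direction of that table was itself read from the sign of these genes. Of 3403 genes called here with a log2 fold change of at least 2 in size, 2620 were in that table.

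Most muscle genes of the fixed lists were higher in transdifferentiated cells than in MEF. Myod1 stood at 874 ± 445 CPM (SD, n = 2) against 0.983 ± 0.635 in MEF, a rise of 9.81 ± 0.62 on the log2 scale (SE; edgeR adjusted p = 1.0e-05), and the reads may include an introduced copy, since the factor used is not given in the sources used here. Myog (chromosome 1, 134289989 to 134292548) reached 733 ± 187 CPM, and the fusion factors Mymk and Mymx, which myoblasts need to form multinucleated fibres, reached 1159 ± 427 and 224 ± 16.8 CPM from 2.46 ± 1.28 and 0.512 ± 0.101 in MEF. Of 20 myogenic regulators 12 rose (13 adjusted over the list alone), 0 fell and 8 were neither (camera adjusted p = 6.4e-14; adjusted p = 0.078 with an estimated correlation). Core sarcomere genes rose in 33 of 34 cases, over all genes and adjusted over the list alone, with a median of 9.08 (camera adjusted p = 2.1e-93). Cardiac alpha-actin Actc1 (chromosome 2, 114047282 to 114053548), the actin of early muscle, rose from 19.98 ± 0.6001 to 12821 ± 2147 CPM (9.33 ± 0.35, edgeR adjusted p = 1.4e-06), and titin (Ttn) from 4.83 ± 1.62 to 3651 ± 105 CPM. All 18 adult fast fibre genes rose, over all genes and adjusted over the list alone (median 9.20, camera adjusted p = 8.5e-66), as did all 8 embryonic and neonatal genes (camera adjusted p = 1.2e-42) and 14 of 15 slow fibre genes (camera adjusted p = 4.6e-35). The remaining slow fibre member, Tpm3, was lower (-0.98 ± 0.24, edgeR adjusted p = 0.0167). Tpm3 was not called without Transdifferentiated replicate 1 or 2 (adjusted p = 0.0619 and 0.0596). Fast troponins Tnnt3 and Tnni2 rose by 9.32 ± 0.34 and 9.52 ± 0.35 on the log2 scale, and fast myosin Myh4 was at 153 ± 0.5503 CPM against 3 counts in the 2 MEF libraries together. Its ratio to MEF was 1969.7 (Poisson interval 674 to 9551). Excitation-contraction coupling and synapse genes rose in 24 of 25 cases (25 adjusted over the list alone, camera adjusted p = 6.4e-53; adjusted p = 0.0765 with an estimated correlation), and energy metabolism genes in 23 of 24 (24 adjusted over the list alone, camera adjusted p = 4.8e-41). Myoblast fusion and cell surface genes rose in 12 of 17 cases, over all genes and adjusted over the list alone, while Myof and Met fell, Myof named after its values were seen (camera adjusted p = 1.4e-11; adjusted p = 0.199 with an estimated correlation). Notch pathway genes rose in 6 of 15 cases and fell in 4, over all genes and adjusted over the list alone, with a median of -0.01 and a mean of 1.53 (camera adjusted p = 0.0332, direction higher; adjusted p = 0.497 with an estimated correlation). That call was lost without MEF replicate 2, Muscle replicate 2 or Transdifferentiated replicate 2 (adjusted p = 0.179, 0.0620 and 0.126). Among genes outside the lists, the secretin receptor Sctr was at 0 in both MEF libraries and at 28.4 ± 0.451 CPM in transdifferentiated cells, at least 182-fold higher.

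**Figure D1:**
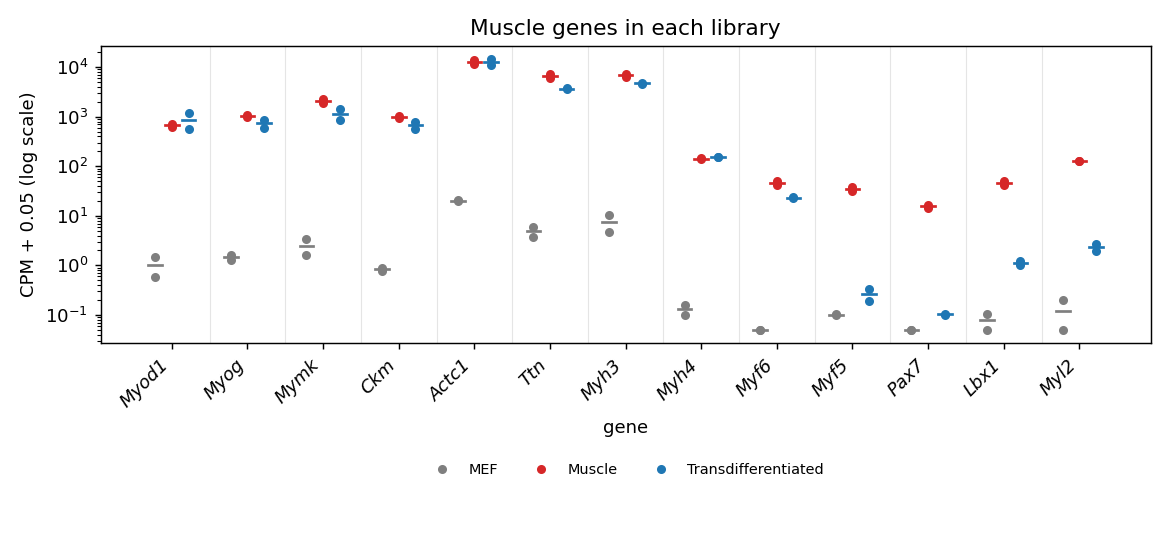
CPM plus 0.05 of 13 muscle genes on a log axis, with points for libraries (2 per group) and bars for group means. Myod1 to Myf6 lay near the muscle level in transdifferentiated cells, whereas Myf5, Pax7, Lbx1 and Myl2 lay far below it, with Myf5 at 0.213 CPM against 34.8 CPM in muscle.

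Oxidative phosphorylation genes showed a smaller change. In transdifferentiated cells 9 of 47 rose, over all genes and adjusted over the list alone, and 38 were neither, with a median of 0.58 (camera adjusted p = 0.0402). That list's adjusted p = 0.497 with an estimated correlation, and it was 0.0820 without Transdifferentiated replicate 1. Ndufa5, a complex I subunit, rose by 1.63 ± 0.36 on the log2 scale (edgeR adjusted p = 0.00967). Of 13 genes on the mitochondrial genome 8 were higher (9 adjusted over the list alone, camera adjusted p = 0.0111), with mt-Nd2 at 775 ± 74.9 CPM in MEF and 2238 ± 66.1 CPM in transdifferentiated cells. The mitochondrial list's adjusted p = 0.346 with an estimated correlation, and it was 0.481 with a GC offset, chosen after seeing the data.

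Most cell-cycle and contractile fibroblast genes and 13 of 24 TGF-beta and BMP targets fell in transdifferentiated cells. Of 45 cell-cycle genes 32 fell (38 adjusted over the list alone), 0 rose and 13 were neither, with a median of -1.54 (camera adjusted p = 9.5e-12; adjusted p = 0.162 with an estimated correlation). Mki67 was at 28.2 ± 9.08 CPM against 76.4 ± 15.1 CPM in MEF (-1.44 ± 0.32, edgeR adjusted p = 0.0107), and the mitotic kinase Aurka had a log2 fold change of -2.30 ± 0.36. Contractile fibroblast and smooth muscle genes fell in 11 of 15 cases, over all genes and adjusted over the list alone, and 2 rose (camera adjusted p = 6.0e-06; adjusted p = 0.314 with an estimated correlation). Smooth muscle calponin Cnn1 went from 343 ± 60.7 to 9.78 ± 0.00106 CPM, while Synpo2, a Z-disc protein also made in skeletal muscle, rose from 14.7 ± 1.96 to 522 ± 105 CPM. Adjusted over the list alone 14 of the TGF-beta and BMP targets fell; over all genes 3 rose and 8 were neither (median -1.20, camera adjusted p = 1.8e-06; adjusted p = 0.122 with an estimated correlation). The BMP antagonist Grem1 had a log2 fold change of -4.93 ± 0.31 (edgeR adjusted p = 9.8e-06). The 3 members that rose, Tgfb2, Bmp2 and Mstn, are secreted ligands, and Tgfb2 and Bmp2 were named after their values were seen.

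Fibroblast identity and matrix genes moved both ways. Fibroblast identity genes fell in 15 of 34 cases, over all genes and adjusted over the list alone, 4 rose (6 adjusted over the list alone) and 15 were neither (median -0.85, camera adjusted p = 0.00242; adjusted p = 0.199 with an estimated correlation). Thy1 (chromosome 9, 44043384 to 44048579) fell from 755 ± 255 to 102 ± 32.5 CPM and Ly6a from 472 ± 13.9 to 36.6 ± 10.2 CPM. The members that rose were Pi16, Tbx15, Lhx9 and Runx1, of which Pi16 and Runx1 were named after their values were seen, and Lhx9 was not called when any single library was left out (adjusted p = 0.153 without MEF replicate 2). Matrix genes fell in 20 of 44 cases (23 adjusted over the list alone), 4 rose (5 adjusted over the list alone) and 20 were neither (camera adjusted p = 7.8e-05; adjusted p = 0.497 with an estimated correlation). Thrombospondin Thbs1 had a log2 fold change of -3.12 ± 0.32 (edgeR adjusted p = 1.8e-04), whereas the elastic fibre protein Mfap4 rose by 2.68 ± 0.36 (edgeR adjusted p = 7.5e-04). Type I collagen Col1a1 was at 13546 ± 6468 CPM in MEF and 7109.9 ± 2699 CPM in transdifferentiated cells, a difference within the spread between replicates (edgeR adjusted p = 0.169). Hox genes fell in 18 of 37 cases (21 adjusted over the list alone), none rose and 19 were neither (median -1.36, camera adjusted p = 5.6e-07; adjusted p = 0.343 with an estimated correlation). Hoxb9 and Hoxc11 had log2 fold changes of -2.30 ± 0.26 and -3.31 ± 0.39 (edgeR adjusted p = 2.8e-04 and 3.8e-04).

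Nearly all macrophage markers were higher in transdifferentiated cells than in MEF, and imprinted genes moved both ways. Of 30 imprinted genes, which are expressed from the allele of a single parent, 15 rose, over all genes and adjusted over the list alone, 5 fell (6 adjusted over the list alone) and 10 were neither (median 1.05, camera adjusted p = 0.0161; adjusted p = 0.185 with an estimated correlation). Peg10 (chromosome 6, 4747306 to 4760517) rose from 156 ± 7.81 to 2354 ± 322 CPM and Zdbf2 from 13.1 ± 3.29 to 476 ± 88.3 CPM (edgeR adjusted p = 7.3e-05 and 1.0e-05). The 5 that fell were Grb10, Ndn, Nnat, Sgce and Impact, the last 4 named after their values were seen. Macrophage and leukocyte markers rose in 16 of 17 cases (17 adjusted over the list alone) with a median of 3.31 (camera adjusted p = 1.4e-11; adjusted p = 0.115 with an estimated correlation). Their median level was 3.004 CPM in MEF and 35.8 CPM in transdifferentiated cells. The complement gene C1qa (chromosome 4, 136895917 to 136898803) rose from 1.36 ± 0.135 to 46.2 ± 3.62 CPM, and the Fc receptor chain Fcer1g from 6.89 ± 1.63 to 61.7 ± 8.64 CPM (edgeR adjusted p = 1.1e-05 and 4.2e-04). In the same libraries inflammatory secreted factors fell in 8 of 15 cases and rose in 2, over all genes and adjusted over the list alone (median -1.75, camera adjusted p = 3.9e-04; adjusted p = 0.162 with an estimated correlation), and the chemokine Ccl2 went from 234 ± 42.7 to 25.5 ± 3.42 CPM. Interferon response genes had no list call (3 of 27 rose and 5 fell, 3 and 8 adjusted over the list alone, camera adjusted p = 0.107).

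Genes of the DNA methylation machinery did not move as a set (7 of 22 rose, 3 fell, camera adjusted p = 0.945; 7 and 4 adjusted over the list alone). Its median was 0.08 and its mean 0.05, while camera's direction was lower. The dioxygenases Tet1 (chromosome 10, 62804570 to 62908996) and Tet2, which oxidise 5-methylcytosine, rose by 3.27 ± 0.38 and 1.70 ± 0.28 on the log2 scale (edgeR adjusted p = 3.3e-04 and 0.00232). Uhrf1, which recruits the maintenance methyltransferase, had a log2 fold change of -1.88 ± 0.36 (edgeR adjusted p = 0.0049), alongside the cell-cycle genes. The maintenance methyltransferase Dnmt1 itself was at 81.6 ± 17.4 CPM in MEF and 48.4 ± 9.397 CPM in transdifferentiated cells (log2 fold change -0.75 ± 0.27, edgeR adjusted p = 0.073), and Dnmt3b at 1.399 ± 0.124 and 0.725 ± 0.0708 CPM (edgeR adjusted p = 0.261). The de novo methyltransferase Dnmt3a was higher, at 14.95 ± 0.743 and 31.3 ± 1.52 CPM (edgeR adjusted p = 0.0178). Dnmt3a was not called without MEF replicate 1, MEF replicate 2 or Transdifferentiated replicate 2 (adjusted p = 0.0574, 0.0705 and 0.0718). Of the pluripotency list 4 of its genes passed the count filter and Esrrb alone rose, from 0 counts to 12.8 ± 5.57 CPM, at least 82.1-fold; it stood at 18.2 ± 3.07 CPM in muscle. Over all tested genes 2769 rose and 1973 fell in transdifferentiated cells against MEF (edgeR, adjusted p under 0.05). The lower count was 1280 without Transdifferentiated replicate 1.

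**Figure D2:**
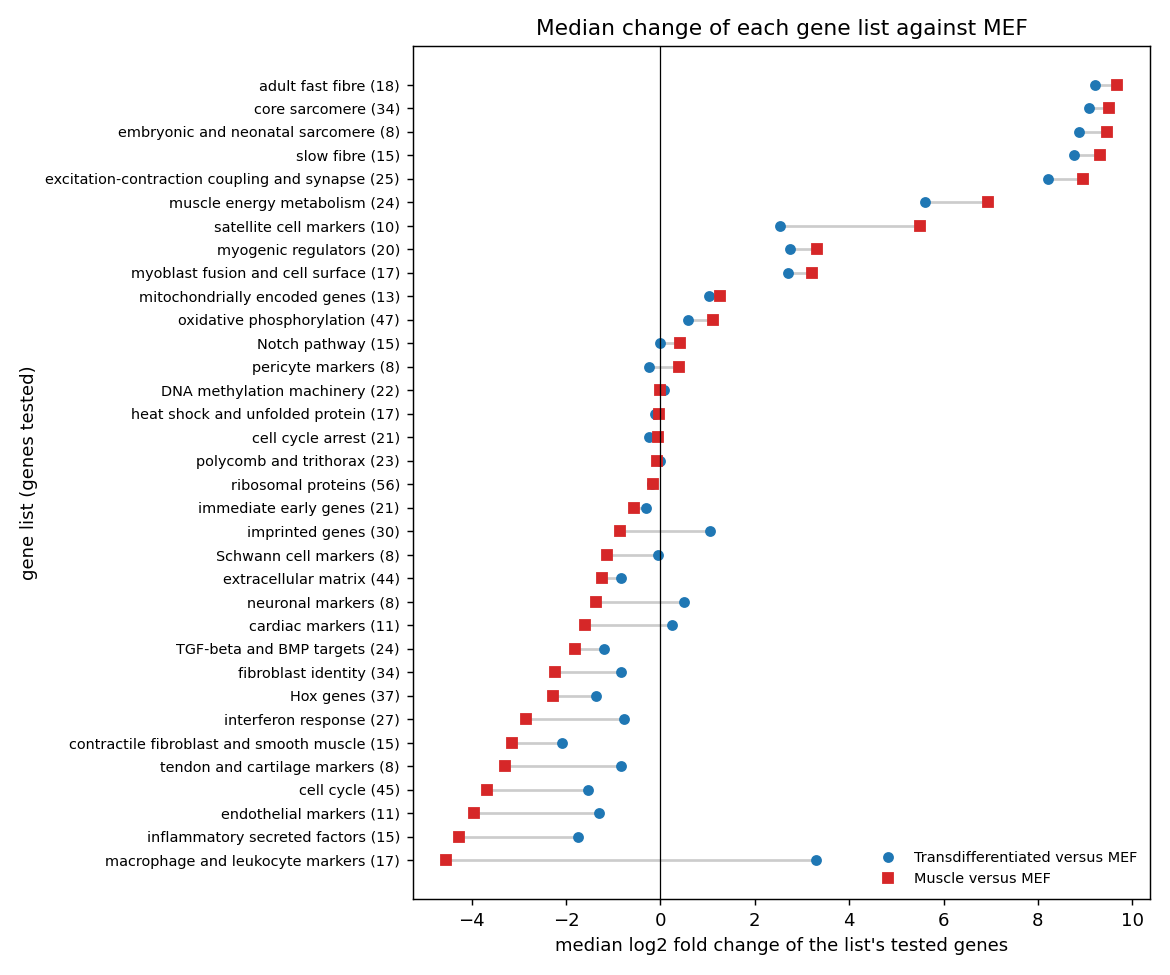
Median log2 fold change against MEF of each gene list with at least 8 tested genes, for transdifferentiated cells (circles) and muscle (squares). Core sarcomere genes lay at 9.08 and 9.50, while macrophage markers lay at 3.31 in transdifferentiated cells and -4.54 in muscle.

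Set directly against muscle, most sarcomere genes were not called, which does not show them to be equal. The median log2 differences of the core sarcomere and adult fast fibre lists were -0.28 and -0.13. Those of the slow fibre and excitation-contraction coupling lists were -0.81 and -0.67. Myf5, Pax7 and Lbx1 were far lower in transdifferentiated cells. Myf5 (chromosome 10, 107482908 to 107486134), a regulator of myoblast commitment, was at 34.8 ± 5.41 CPM in muscle and 0.213 ± 0.09605 CPM in transdifferentiated cells (SD, n = 2), a log2 difference of -7.33 ± 0.46 (SE; edgeR adjusted p = 1.0e-04). Pax7 (chromosome 4, 139737062 to 139833528), the marker of muscle stem cells, was at 15.6 ± 1.44 CPM in muscle against 2 counts in both transdifferentiated libraries together, a ratio of 299 (Poisson interval 82.8 to 2471; edgeR adjusted p = 2.5e-04). Lbx1, a factor of migrating limb muscle precursors, was at 46.2 ± 5.05 and 1.06 ± 0.146 CPM (edgeR adjusted p = 1.8e-04). Of 20 myogenic regulators 16 were not called, including Myod1 (0.38 ± 0.41) and Myog (-0.51 ± 0.26), Vgll2 was higher, and 3 were lower, among them Myf5 and Pax7 (6 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.1e-05; adjusted p = 0.192 with an estimated correlation). Vgll2 was not called without Muscle replicate 2 (adjusted p = 0.108). Satellite cell markers, a list that also holds Pax7 and Myf5, were lower in 3 of 10 cases (6 adjusted over the list alone) and higher in 1 (camera adjusted p = 4.6e-07; adjusted p = 0.192 with an estimated correlation).

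Core sarcomere genes were not called in 29 of 34 cases, over all genes and adjusted over the list alone, and their median of -0.28 was slightly below that of muscle (camera adjusted p = 0.00718; adjusted p = 0.475 with an estimated correlation, and 0.0803 without Transdifferentiated replicate 1). The exceptions were Xirp2, higher, and Neb, Tcap, Nrap and Mypn, lower, of which Tcap and Nrap were named after their values were seen. Xirp2, Neb and Mypn were not called without Muscle replicate 2 (adjusted p = 0.106, 0.157 and 0.0580), Xirp2 and Mypn without Muscle replicate 1 (0.177 and 0.0757) and Neb without Transdifferentiated replicate 2 (0.0515). Skeletal actin Acta1 (chromosome 8, 123891769 to 123894751) stood at 26184 ± 4236 CPM in muscle and 25574 ± 9474 CPM in transdifferentiated cells, with a log2 difference of -0.03 ± 0.34 (edgeR adjusted p = 0.981). Slow fibre genes were lower in 5 of 15 cases (6 adjusted over the list alone, camera adjusted p = 1.7e-04; adjusted p = 0.192 with an estimated correlation), and the slow light chain Myl2 had a log2 difference of -5.79 ± 0.42 (edgeR adjusted p = 1.8e-04). The other lower members were Myh7, Tnni1, Tpm3 and Pln, of which Pln was named after its values were seen. Myh7, Tnni1 and Tpm3 were not called without Muscle replicate 1 (adjusted p = 0.138, 0.216 and 0.0818), Muscle replicate 2 (0.105, 0.121 and 0.331) or Transdifferentiated replicate 1 (0.109, 0.233 and 0.123), nor Tpm3 without Transdifferentiated replicate 2 (0.126). Excitation-contraction coupling and synapse genes were lower in 5 of 25 cases (8 adjusted over the list alone, camera adjusted p = 4.2e-07; adjusted p = 0.192 with an estimated correlation). The receptor kinase Musk, which assembles the neuromuscular junction, was at 219 ± 55.1 and 31.8 ± 11.1 CPM (edgeR adjusted p = 0.00189). Of 18 adult fast fibre genes 2 were higher and 2 lower (2 and 5 adjusted over the list alone) and 14 were neither (camera adjusted p = 0.0272; adjusted p = 0.221 with an estimated correlation, 0.109 without Transdifferentiated replicate 1, 0.0760 without Muscle replicate 2 and 0.0630 with the GC offset, chosen after seeing the data). The higher members were Myh2 and Mylk2, the latter named after its values were seen, and the lower ones Mybpc2 and Casq1. Myh2 and Mybpc2 were not called without Muscle replicate 2 (adjusted p = 0.236 and 0.0619), nor Myh2 without Transdifferentiated replicate 2 (0.0612). Casq1, the calcium-binding protein of the fast sarcoplasmic reticulum, was at 781 ± 83.7 and 132 ± 6.09 CPM (edgeR adjusted p = 4.0e-04). The hormone gene Fgf21 was at 50.2 ± 12.4 CPM in muscle and 2.95 ± 0.278 CPM in transdifferentiated cells.

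Most cell-cycle genes were higher than in muscle, as were some fibroblast identity, Hox and imprinted genes. Of 45 cell-cycle genes 28 were higher in transdifferentiated cells (33 adjusted over the list alone), 1 (Cdk2) was lower and 16 were neither (median 1.79, camera adjusted p = 7.1e-15; adjusted p = 0.192 with an estimated correlation). Mki67 (chromosome 7, 135689784 to 135716361) differed by 3.94 ± 0.37 on the log2 scale (edgeR adjusted p = 4.0e-04), and the call of Cdk2 ended without Muscle replicate 1, Muscle replicate 2 or Transdifferentiated replicate 1 (adjusted p = 0.0813, 0.168 and 0.106). Fibroblast identity genes were higher in 14 of 34 cases (16 adjusted over the list alone), 1 (Eng) was lower (2 adjusted over the list alone) and 19 were neither (median 0.75, camera adjusted p = 2.8e-07; adjusted p = 0.112 with an estimated correlation). Cd34, a marker of interstitial progenitors, was at 2.26 ± 0.182 CPM in muscle and 25.4 ± 5.62 CPM in transdifferentiated cells (edgeR adjusted p = 3.5e-04), while Eng was not called without Muscle replicate 1 (adjusted p = 0.1496). Matrix genes were higher in 12 of 44 cases (14 adjusted over the list alone), 1 was lower (5 adjusted over the list alone) and 31 were neither (camera adjusted p = 0.00175; adjusted p = 0.614 with an estimated correlation and 0.210 without Muscle replicate 2). The matrix proteoglycan lumican (Lum) was at 46.5 ± 4.16 CPM in MEF, 0.914 ± 0.517 CPM in muscle and 131 ± 45.4 CPM in transdifferentiated cells (transdifferentiated over muscle 7.11 ± 0.48, edgeR adjusted p = 1.4e-04). In the same libraries the macrophage markers stood at a median of 35.8 CPM, against 0.1797 CPM in muscle.

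Hox genes were higher in 14 of 37 cases (15 adjusted over the list alone), 4 were lower (6 adjusted over the list alone) and 19 were neither (camera adjusted p = 0.00379; adjusted p = 0.531 with an estimated correlation). Hoxb9 (chromosome 11, 96271457 to 96276595) was at 81.7 ± 8.49, 0.323 ± 0.02604 and 16.6 ± 0.278 CPM in MEF, muscle and transdifferentiated cells (transdifferentiated over muscle 5.64 ± 0.35, edgeR adjusted p = 1.0e-04). The lower 4 were Hoxc10, Hoxc11, Hoxc12 and Hoxc13, neighbours in a single cluster, with Hoxc10 and Hoxc12 named after their values were seen. Hoxc11 (chromosome 15, 102954427 to 102957708) was at 19.8 ± 1.24 CPM in muscle and 1.196 ± 0.0211 CPM in transdifferentiated cells (edgeR adjusted p = 4.6e-04). Of 30 imprinted genes 14 were higher than in muscle (16 adjusted over the list alone), 3 (Grb10, Cdkn1c and Zim1, the last named after its values were seen) were lower and 13 were neither (median 0.95, camera adjusted p = 2.0e-10; adjusted p = 0.0611 with an estimated correlation). Grb10 was not called without Muscle replicate 1 or 2 (adjusted p = 0.324 and 0.147) or Transdifferentiated replicate 1 or 2 (0.2099 and 0.123). Rian (chromosome 12, 109603940 to 109661716) and Mirg, noncoding transcripts of the Dlk1-Dio3 cluster, were at 83.9 ± 1.46 and 7.49 ± 2.07 CPM in muscle, 583 ± 179 and 69.3 ± 19.9 CPM in MEF and 2919.7 ± 563 and 295 ± 74.3 CPM in transdifferentiated cells. They exceeded muscle by 5.12 ± 0.33 and 5.29 ± 0.39 on the log2 scale (edgeR adjusted p = 1.3e-04 and 1.8e-04). The amino acid transporter Slc38a4 was higher by 5.84 ± 0.31, at 151 ± 8.18 CPM against 113 ± 17.1 in MEF. Macrophage markers were higher in the same libraries.

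Macrophage and leukocyte markers showed the largest median difference from muscle of the lists with at least 8 tested genes. In transdifferentiated cells 16 of 17 were higher (17 adjusted over the list alone), with a median of 8.25, or 7.55 with genes at 0 in muscle set to their bound (camera adjusted p = 7.6e-60). This was the 1 list call of this comparison with an adjusted p under 0.05 with an estimated correlation (adjusted p = 0.0149). For macrophage and leukocyte markers it was lost when a GC offset, chosen after seeing the data, was used with the estimated correlation (adjusted p = 0.0963). The colony-stimulating factor receptor Csf1r (chromosome 18, 61100598 to 61132149) was at 0.676 ± 0.00905 CPM in muscle and 55.96 ± 11.3 CPM in transdifferentiated cells (edgeR adjusted p = 9.5e-05), and the signalling adaptor Tyrobp was at 0 in both muscle libraries and 44.7 ± 1.33 CPM in transdifferentiated cells, at least 288-fold higher. Interferon response genes, unlike the macrophage markers, had no list call against MEF (median -0.76). Against muscle 15 of 27 were higher (21 adjusted over the list alone), none was lower and 12 were neither (median 2.04, camera adjusted p = 1.6e-11, and 0.0611 with an estimated correlation). Ifi27l2a was at 0.213 ± 0.302 and 31.7 ± 7.83 CPM (edgeR adjusted p = 6.0e-04). Inflammatory secreted factors were higher in 8 of 15 cases (9 adjusted over the list alone, camera adjusted p = 1.0e-07; adjusted p = 0.137 with an estimated correlation), among them the chemokine Cxcl12 at 2.72 ± 0.1102 CPM in muscle, 79.8 ± 11.5 CPM in transdifferentiated cells and 538 ± 158 CPM in MEF. Of 56 ribosomal protein genes 0 were called, over all genes and adjusted over the list alone (median 0.02, mean 0.03, camera's direction lower, camera adjusted p = 0.486).

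**Figure D3:**
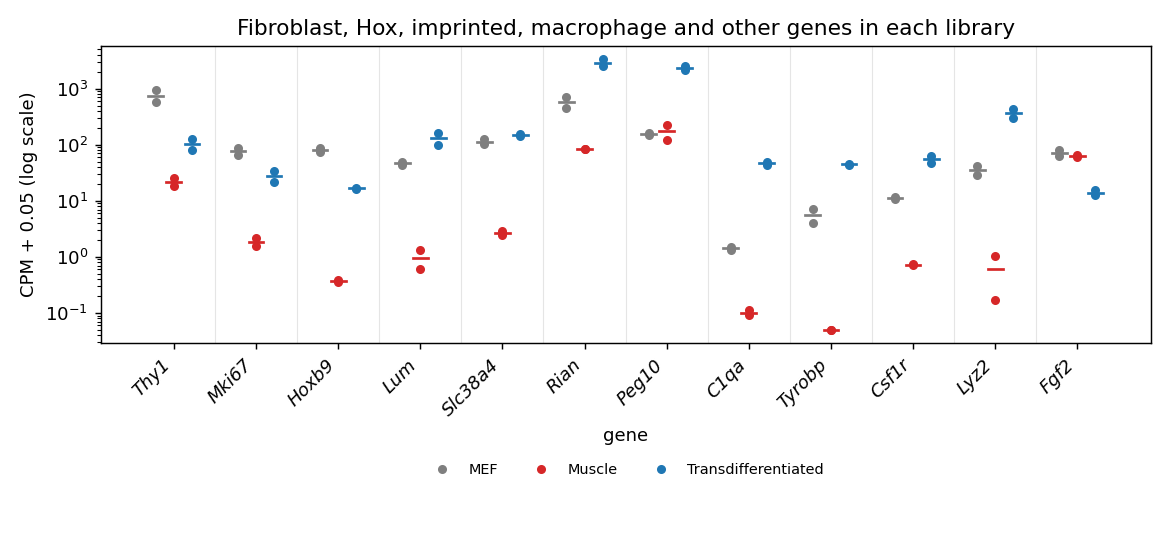
CPM plus 0.05 of 12 fibroblast, cell-cycle, Hox, imprinted, macrophage and other genes on a log axis, with points for libraries (2 per group) and bars for group means. C1qa, Tyrobp, Csf1r, Rian and Peg10 were higher in transdifferentiated cells than in both other groups, and Fgf2 lower, at 13.9 CPM against 72.3 in MEF and 63.3 in muscle.

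Over all tested genes 1319 were higher and 428 lower in transdifferentiated cells than in muscle (edgeR, adjusted p under 0.05), so that 75.5% of the calls were higher. The counts were 743 and 165 without Muscle replicate 1 and 589 and 140 without Muscle replicate 2, the lower count was 228 without Transdifferentiated replicate 1, and a GC offset chosen after seeing the data gave 2162 and 1044. Genes on the X or Y chromosome made up 82 of the 1747 calls.

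The changes from MEF were set side by side to ask which part of the muscle difference the transdifferentiated cells shared. Of 2755 genes higher in muscle than in MEF by at least 1 on the log2 scale, 1981 (71.9%) were also higher in transdifferentiated cells, 11 were lower and 763 were not called. Of 2936 genes lower in muscle, 1519 (51.7%) were lower, 130 were higher and 1287 were not called, and without Muscle replicate 2 the count of 1519 was 995. Independent lists of these sizes would share 438 and 333 genes. A simulated unchanged group, drawn from the MEF means, shared 0.15 and 0.1 on average, which is near 0 by its design. The fold changes correlated across genes, which are not independent replicates, with Pearson r of 0.769 and Spearman rho of 0.744 against a simulated r of 0.109. Their covariance was 3.79 against 0.148 in the simulation. A split of the controls would leave 1 MEF library on each side and was not made. Part of the excess over independent lists may come from the shared controls.

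On the log2 scale sarcomere genes covered nearly the whole distance from MEF to these muscle samples. Fibroblast, cell-cycle and Hox genes covered a smaller part of it. The muscle libraries held 150625 and 119956 counts of embryonic myosin Myh3, against 3457 and 2288 of fast myosin Myh4. Skeletal actin Acta1, at 684265 and 381012 counts, exceeded the early actin Actc1, at 321055 and 191358. The stage and source of this muscle were not tested, so the shares need not hold for adult muscle tissue. Shares per list were not computed on the CPM scale. A gene with a large change can cover most of the log2 distance and still lie well below muscle. Neb, 1 of 4 core sarcomere genes called lower than muscle (1 was higher), rose by 7.71 against 9.34 in muscle. Its levels were 1413 CPM in transdifferentiated cells and 4387 CPM in muscle. The median share covered was 96.7% for core sarcomere genes, 98.7% for adult fast fibre genes, 89.9% for excitation-contraction coupling genes and 60.0% for oxidative phosphorylation genes. Among genes lower in muscle it was 79.0% for matrix genes, 48.9% for cell-cycle genes, 48.7% for fibroblast identity genes, 29.8% for Hox genes and 27.7% for interferon response genes. The 15 imprinted genes lower in muscle had a median of 0.477%, with 19.8% and 9.40% in the transdifferentiated libraries taken alone. This value is not firm. The 14 macrophage markers lower in muscle had -59.8% (-86.0% and -71.9% in the libraries taken alone), that is, beyond MEF on the side away from muscle. Over all genes the median was 85.5% (quartiles 64.7% to 101%) for genes higher in muscle and 57.1% (quartiles 23.4% to 85.1%) for genes lower in muscle. Each transdifferentiated library taken alone gave 83.6% and 84.6% for the former and 57.6% and 57.3% for the latter. Values for a library alone, here and above, use log2 CPM with a small offset and not the fitted fold changes. They are another measure and need not lie on both sides of the fitted median. These shares are descriptions with no test, and the difference between the directions was not tested. The groups also differed in sex-linked transcripts, so differences in the source of the cells cannot be separated from conversion in them. The order of the directions depended on the scale: on the CPM scale the shares were 66.9% for genes higher and 77.4% for genes lower in muscle, the reverse order. With a threshold of 3 on the log2 scale they were 91.1% and 26.8%.

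**Figure D4:**
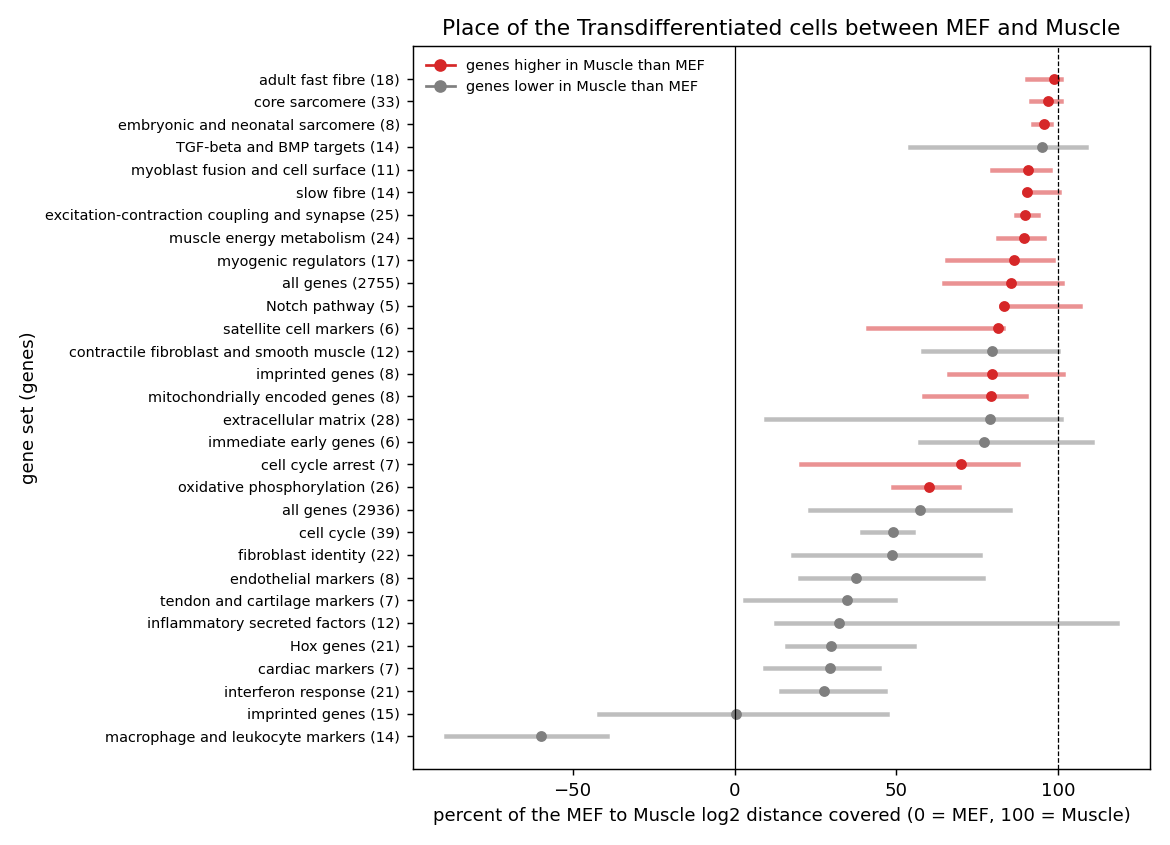
Share of the log2 distance from MEF (0) to muscle (100) covered by transdifferentiated cells, in percent, per gene set with the number of genes in parentheses, points for medians and lines between the quartiles, for genes higher (red) or lower (grey) in muscle than in MEF. Sarcomere sets lay near 100, with 96.7% for the core set, and macrophage markers at -59.8%.

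Some genes set transdifferentiated cells apart from both references. In all 456 genes were higher and 106 lower than in both MEF and muscle (edgeR, adjusted p under 0.05 in both). The simulation with an unchanged group gave 0.15 and 0.05, which is near 0 by its design and does not bear on why these genes differ. Among the 8 named by the fixed rule, the coagulation factor F13a1 (chromosome 13, 36867178 to 37050244), also made by macrophages, was at 0.1004 ± 0.0641, 0.0853 ± 0.121 and 40.8 ± 7.54 CPM in MEF, muscle and transdifferentiated cells, the matrix gene Tnn at 1.203 ± 0.222, 0.0426 ± 0.0603 and 52.9 ± 3.99 CPM, and Mgam, an intestinal glucosidase, at 0.732 ± 0.211, 1.33 ± 0.01205 and 33.8 ± 8.24 CPM. The membrane protein gene Atp1b4 (chromosome X, 38316184 to 38336769) was at 2.77 ± 1.94 CPM in muscle and 189 ± 14.4 CPM in transdifferentiated cells (edgeR adjusted p = 2.8e-04). Ms4a7, C1qa, Fcrls and Adgre1, all known from macrophages, were the other members of the 8. Lower than in both was the growth factor Fgf2, at 13.9 ± 2.02 CPM against 72.3 ± 13.95 in MEF and 63.3 ± 2.68 in muscle. The counts were 287 and 40 without Muscle replicate 1, 236 and 49 without Muscle replicate 2, 63 for the lower genes without Transdifferentiated replicate 1, and 810 and 260 with the GC offset.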

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

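The GC offset and the crossed pairing were chosen only after the data were seen. No list or named gene called in the main fit reversed its direction under any alternative run. Those not called were not checked for this. The balance of the muscle against MEF counts did turn, from 3009 higher and 3189 lower to 4301 and 4133 with the GC offset. Counts of calls stayed within 1.5 times of the reported value under RLE, upper-quartile and library-size scaling, DESeq2, limma-voom, both other dispersion settings and fits of the compared groups alone. At an adjusted p under 0.01, by construction, the counts higher and lower were 1642 and 927 for transdifferentiated cells against MEF, 1899 and 1992 for muscle against MEF and 657 and 139 for transdifferentiated cells against muscle. Without the count filter, which tests more genes, 670 genes were lower in transdifferentiated cells than in muscle and the correlation of fold changes was 0.652; the cause was not tested. With the GC offset transdifferentiated cells against muscle had 2162 and 1044 calls and 810 and 260 genes apart from both; the cause was not tested, and 1745 of the 1747 reported calls were shared. Library-size scaling put the median log2 fold change of all genes between transdifferentiated cells and muscle at 0.11, and the GC offset put that against MEF at 0.12.

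Leaving out 1 library in turn assumes that the lone library of a group varies like the others. The counts then ranged from 2258 to 2394 higher and 1280 to 1926 lower for transdifferentiated cells against MEF, 1980 to 3223 and 1778 to 3445 for muscle against MEF, and 589 to 1616 and 140 to 605 for transdifferentiated cells against muscle. The genes apart from both ranged from 236 to 475 and 40 to 126, and the shared lower genes from 995 to 1563. The distance covered ranged from 83.6% to 87.7% for genes higher and 50.5% to 63.8% for genes lower in muscle. Of 313 named genes per comparison, 39 of 244, 29 of 264 and 72 of 175 calls were lost in at least 1 such fit. In the other settings 32, 9 and 31 were lost, 27, 7 and 29 of them with the replicate block.

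The distance covered, whose replicates lie close together, moved to 84.3% and 58.7% with RLE, 88.2% and 55.9% with library size, and 84.3% and 58.9% with DESeq2, and to 66.9% and 77.4% on the CPM scale, which reverses the order of the directions, and 91.1% and 26.8% at a threshold of 3 on the log2 scale. For genes lower in muscle it was 56.4% without the filter and 54.1% with the GC offset; the cause of these shifts was not tested. With an estimated correlation camera called 5, 10 and 1 lists, and 6, 6 and 0 with the GC offset as well. Fry, which does not compare a list with other genes, called 26, 31 and 20.

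The replicate numbers did not pair the samples across all groups. Deviations of same-numbered libraries went together between MEF and muscle, with a correlation of 0.65. Those of transdifferentiated libraries ran the other way, with -0.86 against MEF and -0.61 against muscle. After the GC offset the correlations were 0.382 between MEF and muscle, -0.680 between MEF and transdifferentiated cells and -0.332 between muscle and transdifferentiated cells. With the replicate number as a block, 265 genes were lower in transdifferentiated cells than in muscle and 68 apart from both, and the distance for lower genes was 56.1%; with the GC offset and the block the values were 680, 170 and 54.8%. With the transdifferentiated numbers exchanged in the block, the counts were 4521 and 3828 against MEF, 4716 higher for muscle against MEF, and 2662 and 1762 against muscle. The cause of the block's shifts was not tested. Depth limited low genes: Pax7 had 0 counts in MEF, where the bound for the group is 0.155 CPM, and Myf5 had 2 counts there.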

Other observations

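The GC offset, the crossed pairing, both tests of the replicate axis and the test of macrophage genes switched on within converted cells were chosen only after the result was seen; the other tests were set before. Genes of the sex chromosomes separated the groups. Muscle had the transcripts of female cells, while MEF and transdifferentiated cells held Y-linked transcripts. Sex, and so the source of the cells, thus differed between muscle and the other groups. MEF held Xist (137 CPM) beside the Y-linked transcripts, as cells of both sexes together would. Xist was lower in transdifferentiated cells (19.6 CPM), so their sex make-up may differ from that of these MEF too. Against MEF, 2 of 5 sex-linked genes were higher in transdifferentiated cells and 1 was lower. Such differences of source cannot be separated from conversion here. Xist (chromosome X, 103460366 to 103483254), transcribed from the inactive X of female cells, was at 508 ± 153 CPM in muscle, 137 ± 28.2 CPM in MEF and 19.6 ± 4.02 CPM in transdifferentiated cells (SD, n = 2). The Y-linked Kdm5d was at 7.36 ± 2.705 CPM in MEF and 13.5 ± 2.601 CPM in transdifferentiated cells against 1 count in both muscle libraries together, and Ddx3y was at 0 in muscle. In transdifferentiated cells against muscle all 4 Y-linked genes of the sex-linked list were higher and Xist was lower (camera adjusted p = 2.1e-06; adjusted p = 0.2 with an estimated correlation). X- or Y-linked genes made up 186 of 4742 calls in transdifferentiated cells against MEF, 233 of 6198 in muscle against MEF and 82 of 1747 in transdifferentiated cells against muscle.

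Some endothelial, tendon, Schwann cell, neuronal and adipocyte markers were higher in transdifferentiated cells than in muscle, while the pericyte, cardiac and keratinocyte lists were not called (camera adjusted p = 0.562, 0.416 and 0.255). Endothelial markers were higher in 4 of 11 cases (camera adjusted p = 3.0e-04; adjusted p = 0.175 with an estimated correlation), with Flt1 at 31.6 ± 2.73, 1.24 ± 0.309 and 9.14 ± 0.287 CPM in MEF, muscle and transdifferentiated cells. Tendon and cartilage markers were higher in 4 of 8 (camera adjusted p = 4.2e-07; adjusted p = 0.192 with an estimated correlation), and Tnmd, a tendon gene, had mean levels of 58.6, 0.0213 and 4.34 CPM. Schwann cell markers were higher in 4 of 8 cases, neuronal markers in 4 of 8 with 1 lower, and adipocyte markers in 2 of 6 (camera adjusted p = 0.00119, 0.0148 and 0.017; adjusted p = 0.221, 0.192 and 0.192 with an estimated correlation, and 0.0616 for adipocyte markers without Muscle replicate 2). Upk3b, known from mesothelium, was at 61.1 ± 11.95 CPM in MEF, 0 in muscle and 21.1 ± 4.95 CPM in transdifferentiated cells, at least 136-fold above muscle. Further genes of the imprinted Dlk1-Dio3 cluster, named after their values were seen, followed Rian: Meg3 was at 1062 ± 445, 223 ± 114 and 3877 ± 1368 CPM and Dlk1 at 206 ± 88.8, 1.602 ± 1.84 and 504 ± 209 CPM. Hes6, a Notch pathway gene of differentiating muscle, rose to 249 ± 54.2 CPM from 11.1 ± 2.48 in MEF, with 206 ± 13.8 in muscle.

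Macrophage genes were higher in transdifferentiated cells than in both references, and 53 of the 63 tested genes of 2 macrophage lists were among the 456 genes above both (11.6% of them). In the second list of leukocyte and macrophage genes, 41 of 46 tested genes (89.1%) were higher than in MEF, with Slc11a1, Arhgap30, Pilra and Cd300lb, named after their values were seen, among the others, which is in line with macrophages being present in these cultures; Lyz2, named after its values were seen, was at 368 ± 102 CPM against 35.3 ± 9.13 in MEF and 0.551 ± 0.607 in muscle. With a GC offset 100% of the 16 calls of the fixed list remained, as did 4718 of the 4742 calls over all genes. Keeping the calls was thus not particular to this list, and it argues against a GC trend between libraries only as it does for calls in general. Activation of macrophage genes within converted cells stays open: the median level rose 11.9 times from MEF, and bulk counts do not say which cells held the transcripts. Whether macrophages came with the MEF, which held these genes at a median of 3.004 CPM, was not tested, and no sort or gate is named in the sources used here.

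In transdifferentiated cells 28 of 45 cell-cycle genes and 14 of 34 fibroblast identity genes were higher than in muscle. If a single fraction of unchanged, unconverted MEF carried all of it, genes nearly absent from muscle would keep about the same ratio to MEF. The ratio was taken over 221 genes at 20 CPM or more in MEF and at least 8 times lower in muscle. It ran from 0.0744 at the 10th percentile through a median of 0.234 to 0.795 at the 90th. That span was 4.65 times the one between the MEF libraries (10.7 against 2.30). It argues against a uniform residual fraction of unchanged MEF as the whole cause for the 221 genes as a set. Only 17 of them were cell-cycle and 9 fibroblast identity genes, with median ratios of 0.256 and 0.157. For these few genes the span decides nothing, and some of the 221 genes were still expressed in muscle. Macrophages as carriers stay open: the 14 fibroblast identity genes above muscle had a median log2 fold change against MEF of -1.23, but transcripts lost on conversion and partly brought back would also lie between muscle and MEF, so the value below 0 set in advance as counting against them decides nothing, and cell-cycle genes were not tested for it. A mixture of partly converted cells may contribute and was not tested.

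Replicates within each group differed along GC content, with Spearman correlations of the replicate difference with GC of -0.769 in MEF, -0.627 in muscle and 0.741 in transdifferentiated cells, so the axis ran the other way in the transdifferentiated pair. After a GC trend was removed from every library the correlation between the MEF and transdifferentiated replicate differences went from -0.860 to -0.680, which argues against GC content as the whole cause. An exchange of single libraries between groups is argued against, since 0 libraries were closer to a library of another group than to their own replicate. This restates the similarities given above, and an exchange of whole groups would not show in it. A shared handling difference with exchanged replicate numbers may remain, and the labels give no batch to test it; no biological explanation was tested.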
